A study of Mus musculus with 10 samples.

How the data were processed

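Microdissected dentate gyrus from 10 mice was used, 5 injected with an adeno-associated virus of serotype 9 carrying Sox11 and 5 with the same serotype carrying GFP, per the labels' protocols. RNA libraries were made with a kit that selects poly(A) RNA and marks strand, per the labels' protocols. The submitters' processing notes list bcl2fastq 1.8.4, cutadapt 1.9.1, STAR 2.5.2a, Subread, featureCounts 1.5.1, DESeq2 1.12.3, R 3.3.1 and the genome build GRCm38. The strand setting of the counting, the annotation release and the treatment of reads that map to several places are not given in the sources used here.

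The authors deposited a table of normalized counts, a signal per gene and library made by dividing read counts by a factor for each library, per the labels and the values themselves. It held 48526 gene identifiers and 10 libraries. Every value above 0 was a whole multiple of the library's value of 1 read within a tolerance of 0.01 reads (100% of values), so whole reads were recovered. The factors recomputed from those reads by DESeq2's median-of-ratios method equalled the authors' to 4 digits. The recovered totals were 54305091, 46510924, 51311817, 56040604 and 53697977 reads for GFP 1, 3, 4, 5 and 6, and 66561707, 52241303, 68769808, 45100154 and 51545059 reads for Sox11 1, 2, 3, 6 and 7. The column numbers do not match the numbers in the sample titles, so columns were assigned to groups only. Symbols and coordinates came from GENCODE M21 on GRCm38, which matched 48058 identifiers. No pair of libraries within a group agreed within sampling noise.

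Genes with a mean of at least 10 normalized counts over the 10 libraries were kept, 17007 in all. Values were taken as log2(normalized count + 1), a scale that understates the change of low genes, and Sox11 was compared with GFP libraries by limma 3.58.1 in R 4.3.3, with the trend and robust options, Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Sox11 minus GFP. For Sox11 alone a two-sided exact permutation test over every assignment of 5 of the 10 libraries was added. Gene lists (35, of which 33 with at least 3 tested members) were tested with limma's camera with a preset correlation of 0.01, leaving Sox11 out, and again with an estimated correlation, with fry and on ranks. On simulated counts for the same 17007 genes and libraries, the test recovered 8% of 50 genes changed 1.2-fold, 62% of 50 changed 1.5-fold, 72% of 50 changed 2-fold and 96% of 50 changed 4-fold, with 3 unchanged genes called.

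The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. Named genes were Sox11, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 50 normalized counts and no overlap between the groups, the 3 members of lowest p of each list that passed or had a member past the threshold, and Sox4, Dcx, Tubb3, Tead2, Prox1, Calb1 and Neurod1. Other genes named beside a count were chosen after their values were seen. For each named gene, the share of 31-base words found in no other gene's transcripts and the share of exonic bases covered by other genes were computed, and 9 of 97 named genes had under 90% of their words to themselves. Alternatives were pseudocounts of 0.5 and 8, no filter or a mean of at least 50, TMM scaling, quantile normalization, estimated sample weights, limma without trend and robust, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on recovered reads, thresholds of 0.1 and 0.01, and each library left out. Further alternatives were chosen after seeing the data. The remaining tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.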

Results

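Gene expression was measured by sequencing poly(A)-selected RNA from the dentate gyrus, the part of the hippocampus that holds the granule neurons and makes new neurons in adult life. The tissue came from C57Bl/6 mice aged 8 weeks. In 5 mice an adeno-associated virus had delivered Sox11 to the dentate gyrus on either side, and in 5 control mice the same kind of virus had delivered green fluorescent protein (GFP). Sox11 is a transcription factor of the SoxC family that is expressed in newborn neurons. The comparison asks which transcripts differ when Sox11 is supplied by the virus. Between 45100154 (Sox11 6) and 68769808 (Sox11 3) reads were assigned to genes per library, and 17007 genes had a mean of at least 10 normalized counts. Libraries are named here by the numbers in the deposited table, GFP 1, 3, 4, 5 and 6 and Sox11 1, 2, 3, 6 and 7.

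Sox11 itself (ENSMUSG00000063632, chromosome 12, 27334264 to 27342574, minus strand, GRCm38) was higher in each Sox11 library than in any GFP library. Its level was 1429 ± 115 normalized counts in the GFP group and 12559 ± 4449 in the Sox11 group (mean ± SD, n = 5 each). The GFP libraries lay between 1364 and 1634 normalized counts, and the Sox11 libraries at 11591 (Sox11 1), 10414 (Sox11 2), 20434 (Sox11 3), 9803 (Sox11 6) and 10552 (Sox11 7). The log2 fold change was 3.08 (SE 0.18), with a two-sided exact permutation p of 0.00794, the smallest that assignments of 5 of the 10 libraries can give. Reads from the viral copy and from the mouse gene are not told apart in these counts.

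Cd24a was among the 10 largest increases and is on the list of immature neuron markers. This surface glycoprotein gene (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265) went from 551 ± 133 to 7634 ± 2024 normalized counts (mean ± SD, n = 5 each), a log2 fold change of 3.78 (SE 0.21). Mex3a, which encodes an RNA-binding protein (chromosome 3, 88532395 to 88541396), went from 353 ± 19.1 to 2637 ± 429 normalized counts, a log2 fold change of 2.88 (SE 0.10). Doublecortin, Dcx, the microtubule-associated protein of migrating neurons (chromosome X, 143855842 to 143933311), went from 1242 ± 50.1 to 4292 ± 820 normalized counts, a log2 fold change of 1.77 (SE 0.11). Their limma adjusted p-values were 9.18e-06 for Cd24a, 1.25e-07 for Mex3a and 9.18e-06 for Dcx. Zfp663, a zinc finger gene (chromosome 2, 165351297 to 165368729), had between 1.15 and 8.80 normalized counts in the GFP libraries and between 170 and 350.3 in the Sox11 libraries, the largest log2 fold change among the genes named (5.47, SE 0.38).

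**Figure D1:**
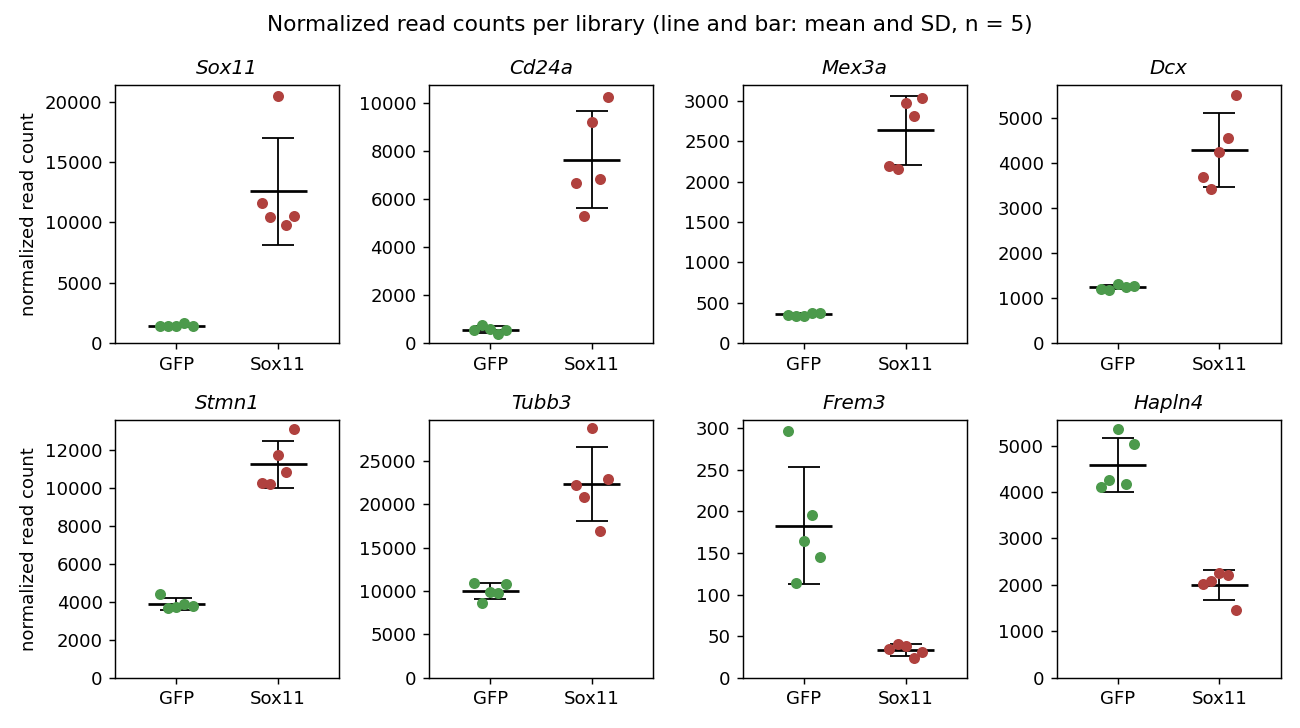
Normalized read counts of 8 genes in each library, with GFP libraries in green and Sox11 libraries in red. Points are libraries, black lines and bars are the mean and SD of 5 libraries, and Sox11, Cd24a, Mex3a, Dcx, Stmn1 and Tubb3 were higher in every Sox11 library than in any GFP library, and Frem3 and Hapln4 were lower.

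In total 3234 of the 17007 genes changed at an adjusted p below 0.05 in limma's moderated test, 1642 of them higher and 1592 lower in the Sox11 libraries. Most changes were small, with a median absolute log2 fold change of 0.32, and 169 genes rose and 42 fell by at least 1 on the log2 scale. The values of the groups did not overlap for 2480 of the changed genes, and for 15.9% of all genes tested, against 0.794% by chance. The other genes among the 10 largest increases were Tspan11 (log2 fold change 2.80), Lemd1 (2.65), Cd1d1 (2.59), Efna4, a ligand of Eph receptors (2.56), Gpc2, a cell-surface heparan sulfate proteoglycan of developing neurons (2.33), and a long noncoding RNA gene, 2410018L13Rik (2.46). Within the libraries numbered 1 to 3 (2 GFP, 3 Sox11) 1013 genes changed, and within those numbered 4 to 7 (3 GFP, 2 Sox11) 2583 changed, a division chosen after seeing the data. With this division as a covariate over all libraries 4048 genes changed, and 3196 of the 3234 kept their call and direction.

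The largest decrease was that of Frem3, an extracellular matrix protein gene (chromosome 8, 80611080 to 80695356), from 183 ± 70.0 to 33.5 ± 6.88 normalized counts (mean ± SD, n = 5 each), a log2 fold change of -2.37 (SE 0.24). Hapln4, which encodes a link protein of perineuronal nets (chromosome 8, 70083457 to 70090862), fell from 4582 ± 575 to 1998 ± 321 normalized counts, a log2 fold change of -1.21 (SE 0.12). Their limma adjusted p-values were 0.000115 and 0.000146. The erythropoietin receptor gene Epor (-1.28), the glycine receptor subunit gene Glra3 (-1.22), Medag (-1.58), Tnfrsf8 (-1.30), Glt8d2 (-1.28), Mfsd13b (-1.19) and Pla2g2f (-1.18), each given as a log2 fold change, were also among the 10 largest decreases. The remaining gene of the 10 was C4bp, with 72.9 ± 11.9 normalized counts in the GFP libraries and 32.4 ± 10.4 in the Sox11 libraries. Lemd1, Gpc2, Medag and 2410018L13Rik share 27.3% to 55.6% of their exonic bases with another gene on the same strand, and Cd1d1 has 75.2% of its 31-base words to itself, so their values are uncertain.

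Of the 26 tested markers of immature neurons, a list fixed beforehand, 15 rose, none fell and 11 did not pass (17 rose when adjusted over the list alone). Stmn1, a microtubule-destabilizing protein of growing neurons, rose by 1.52 on the log2 scale (SE 0.08), Dpysl5 by 0.99 (SE 0.06), Draxin, an axon guidance protein, by 1.79 (SE 0.13) and Tubb3, the neuronal beta-tubulin, by 1.14 (SE 0.12). Of Stmn1's 31-base words 77.6% occur in no other gene. The list test gave an adjusted p of 7.11e-10 with camera's preset correlation, and adjusted p = 0.243 with an estimated correlation. Neurod1 had a log2 fold change of 0.01 (SE 0.09) and Tead2 of 0.56 (SE 0.20), with adjusted p-values of 0.977 and 0.0761 in limma's test. Tead2 passed without GFP 3 (adjusted p = 0.00634), and with each other library left out its adjusted p was up to 0.166. Sox4, another member of the SoxC family, had a log2 fold change of -0.17 (SE 0.09, adjusted p = 0.201), and an opposite-strand gene covers 54.6% of its exonic bases.

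Of the 20 tested genes of the unfolded protein response, the cell's response to misfolded proteins in the endoplasmic reticulum, 11 fell, 1 rose and 8 did not pass, and the counts adjusted over the list alone were the same. Hspa5, the chaperone BiP, fell by 0.56 on the log2 scale (SE 0.06), from 15278 ± 1211 to 10372 ± 687 normalized counts (mean ± SD, n = 5 each). The transcription factor Xbp1 fell by 0.50 (SE 0.05) and the chaperone Hsp90b1 by 0.42 (SE 0.06), while Atf4, also a transcription factor, rose by 0.15. The list's adjusted p was 0.000271 in camera, and adjusted p = 0.243 with an estimated correlation.

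Among the 17 tested targets of p53, 6 rose, 1 fell and 10 did not pass (8 rose and 1 fell when adjusted over the list alone). The cell-cycle inhibitor Cdkn1a rose by 0.64 on the log2 scale (SE 0.12), Eda2r by 1.33 (SE 0.22) and Aen, an apoptosis-enhancing nuclease, by 0.35 (SE 0.05), while Mdm2, the ubiquitin ligase that acts on p53, fell by 0.17. The list's adjusted p was 0.0152 in camera, and adjusted p = 0.243 with an estimated correlation. Of the 18 genes of cholesterol synthesis 6 fell and none rose (8 fell when adjusted over the list alone), among them Stard4 by 0.53 (SE 0.06) and Msmo1 by 0.38 (SE 0.07). Sqle fell by 0.20 (SE 0.05). Without Sox11 1 its adjusted p was 0.0504, the highest with any library left out, and the lowest was 0.0172. The list's adjusted p was 0.00293 in camera, and adjusted p = 0.583 with an estimated correlation.

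Genes of neuronal excitability moved in either direction, with more decreases. Of 42 voltage-gated channel genes 12 fell and 4 rose (13 fell and 4 rose when adjusted over the list alone). The potassium channel subunits Kcns2 and Kcnc2 fell by 0.84 (SE 0.07) and 0.67 (SE 0.08) on the log2 scale, and the sodium channel Scn1a by 0.41 (SE 0.05), while Kcnf1, Cacna1g, Cacna1h and Scn3a rose. Of 14 GABA receptor subunits 4 fell and 1 rose (6 fell and 1 rose when adjusted over the list alone). Gabrd fell by 0.51 (SE 0.10) and Gabra4 by 0.48 (SE 0.09), and Gabra5 rose by 0.48 (SE 0.09). Of 15 interneuron markers 4 fell and none rose (5 fell when adjusted over the list alone), namely Lamp5 (-0.73, SE 0.08), Kcnc2, Npy (-0.42, SE 0.10) and Gad2 (-0.30, SE 0.08), of which Kcnc2 is also on the channel list. The camera adjusted p-values were 0.00578 for channels, 0.0155 for GABA receptors and 0.00578 for interneurons, against adjusted p = 0.715, 0.715 and 0.744 with an estimated correlation. Within the libraries numbered 1 to 3 the median of the interneuron list lay at 0.07, against -0.20 in all libraries.

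Glial and immune markers were higher in part. Of 14 astrocyte markers 4 rose and none fell, over all genes and when adjusted over the list alone. Gfap, the intermediate filament of astrocytes, rose by 0.46 on the log2 scale (SE 0.08), from 18714 ± 2021 to 25754 ± 1648 normalized counts (mean ± SD, n = 5 each), Aldh1l1 rose by 0.22 (SE 0.05), and Acsbg1 rose too. Sox9 rose by 0.29 (SE 0.08), and its call was lost when GFP 4, GFP 5, GFP 6, Sox11 2, Sox11 3 or Sox11 7 was left out (adjusted p of 0.0503 to 0.0640). The astrocyte list passed with an adjusted p of 0.0420 in camera, and adjusted p = 0.715 with an estimated correlation. That call was lost without GFP 1, GFP 6, Sox11 2 or Sox11 6 (adjusted p of 0.0616 to 0.111), and the list median of 0.09 was 0.05 without Sox11 6.

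Of 28 interferon response genes 8 rose and 1 fell (11 rose and 1 fell when adjusted over the list alone). Mx1, an antiviral GTPase, had 3.67 ± 3.26 normalized counts in the GFP libraries and 24.0 ± 18.6 in the Sox11 libraries, and Oasl2 had 210 ± 110 and 616 ± 272 (mean ± SD, n = 5 each). Their log2 fold changes were 2.35 (SE 0.55) and 1.61 (SE 0.37), and Cmpk2, the member that fell, changed by -0.36 (SE 0.06). The list score of GFP 3 (0.38) lay above that of 3 Sox11 libraries, Sox11 2, Sox11 6 and Sox11 7. The list's adjusted p was 8.03e-05 in camera, adjusted p = 0.782 with an estimated correlation and 0.127 in the rotation test fry. Of 20 leukocyte markers 8 reached a mean of 10 normalized counts and were tested. Of these 2 rose, over all genes and when adjusted over the list alone, Ccl5 by 2.00 (SE 0.38) and Cd52 by 1.05 (SE 0.22). Ccl5 (5.25 normalized counts in the GFP libraries, 27.2 in the Sox11 libraries) reached that mean only through the Sox11 libraries. So did Mx1 and Ly6c2 (2.71 and 19.9). The leukocyte list's adjusted p was 0.0389 in camera, and adjusted p = 0.715 with an estimated correlation. That call was lost without GFP 4, GFP 5, GFP 6 or Sox11 1 (adjusted p of 0.0577 to 0.0835). Ly6c2, for which 76.3% of 31-base words are its own, did not pass (log2 fold change 2.06, SE 0.83, adjusted p = 0.112), and passed without Sox11 6 (adjusted p = 0.0269, against up to 0.233 with another library left out).

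**Figure D2:**
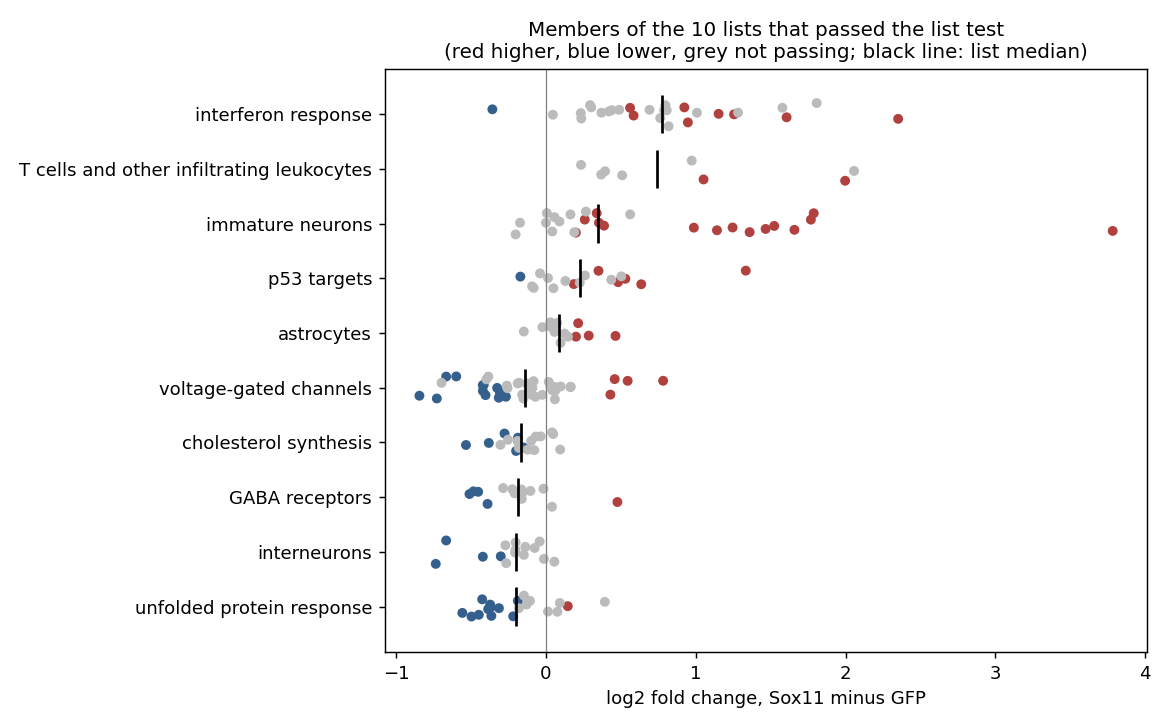
Log2 fold changes (Sox11 minus GFP, horizontal axis) of the members of the 10 gene lists that passed camera's test, 1 point per gene and 1 row per list. Red points were higher, blue points lower, grey points did not pass at an adjusted p of 0.05, and the black line is the list median, from -0.20 for the interneuron and unfolded protein response lists to 0.78 for the interferon response.

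All 10 lists lost their call with an estimated correlation. The rotation test fry called 7 of the 10, without interneurons (adjusted p = 0.0667), leukocytes (0.0667) and the interferon response (0.127), and it also called axon regeneration (0.00162) and mossy cells (0.0464). The rank-based camera called the 10 lists and antigen presentation (adjusted p = 0.0266). In camera with the preset correlation 16 lists passed when GFP 3 was left out. When the 10 libraries were divided at random into 5 and 5, 63 of 100 divisions called at least 10 lists, and only the lists of immature neurons, the unfolded protein response and p53 targets had a p that fewer than 5 divisions matched (1, 1 and 4, the real division included). For the remaining 7 lists between 12 and 32 of the 100 divisions gave a p as small. The divisions were fitted without the column numbers, so a list that differs between those numbers can reach a small p in them.

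The counts in the other lists stand against 9.65% of all tested genes that rose and 9.36% that fell. These lists did not pass camera's test with the preset correlation. Their counts adjusted over the list alone equalled those over all genes, except for activity-regulated genes (5 rose, 7 fell), neuropeptides (1 rose, 5 fell), axon regeneration (6 rose, 3 fell), activated microglia (3 rose, 2 fell) and antigen presentation (0 rose, 1 fell). Mature granule neuron markers had 2 members that rose and 4 that fell out of 20, with Plk5 lower by 0.39 (SE 0.07) on the log2 scale, Gabrd, C1ql2 and Sv2c also lower, and Rfx3 higher. Lct rose by 0.29 (SE 0.09), a call lost without GFP 1, GFP 3, GFP 4, GFP 6, Sox11 6 or Sox11 7 (adjusted p of 0.0506 to 0.0820). The granule neuron markers Prox1 and Calb1 had log2 fold changes of 0.20 (SE 0.15) and 0.16 (SE 0.15), with limma adjusted p-values of 0.398 and 0.527. Activity-regulated genes had 4 that rose and 6 that fell out of 36, among them Rgs4 by -0.31 (SE 0.05), Klf10 by -0.45 (SE 0.08) and Bhlhe40 by -0.44 (SE 0.10). Those that rose were Crem, Egr2, Egr3 and Ier2. Glutamate receptors had 2 that rose and 5 that fell out of 24, among the latter Gria3 by -0.38 (SE 0.07), Gria4 by -0.33 (SE 0.08) and Grm7 by -0.28 (SE 0.07), with Grin2c and Grm3 higher. Of 22 neuropeptide and granin genes 1 rose and 4 fell. Trh rose by 1.92 (SE 0.28), at 5.80 and 24.1 normalized counts, Penk fell by 0.57 (SE 0.11) and Chgb by 0.43 (SE 0.10), and Npy and Scg2 fell too. Axon guidance genes had 5 that rose and 2 that fell out of 42, with Robo3 higher by 0.75 (SE 0.15) and Ephb2 by 0.48 (SE 0.09), Draxin, Efnb2 and Sema6a also higher, and Unc5c and Unc5d lower. Of 18 genes linked to axon regeneration 4 rose and 2 fell, with Tubb3 and Smad1 higher, Stmn4 higher by 0.58 (SE 0.06), Klf7, of which an opposite-strand gene covers 39.4%, by 0.29 (SE 0.06), and Npy and Jun lower. Neural stem and progenitor markers had 1 that rose (Fabp7, 0.40, SE 0.09) and 1 that fell (Hes1, -0.59, SE 0.10) out of 16. Of 20 cell division genes 1 fell (Ccnd2, -0.47, SE 0.06). Hopx (0.14, SE 0.06), Mcm3 (0.24, SE 0.09) and Birc5 (-0.45, SE 0.18), the next members of these lists by p, did not pass.

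Reactive astrocyte and microglia markers had 4 members each that rose and none that fell, out of 24 and 20, where 9.65% of all tested genes rose. Gfap and C4b were among the reactive astrocyte markers that rose. Iigp1 had 200 ± 48.1 normalized counts in the GFP libraries and 459 ± 108 in the Sox11 libraries, and Cxcl10 13.4 and 85.1. C1qb rose by 0.33 (SE 0.06) and C1qc by 0.30 (SE 0.06), and Tyrobp rose too. Laptm5 rose by 0.21 (SE 0.06), a call lost without GFP 1, GFP 5, GFP 6, Sox11 1, Sox11 2, Sox11 3 or Sox11 7 (adjusted p of 0.0650 to 0.0898). Activated microglia markers had 2 that rose, Itgax (1.44, SE 0.31, 89.3% of words its own) and Clec7a, and 2 that fell, Csf1 (-0.26, SE 0.07) and Ctsb, out of 18. Ctsb fell by 0.17 (SE 0.05), a call lost without GFP 1, GFP 3, GFP 4, GFP 6, Sox11 1, Sox11 3, Sox11 6 or Sox11 7 (adjusted p of 0.0508 to 0.0718). Of 21 antigen presentation genes 1 rose (Tap1, 0.75, SE 0.23) and 1 fell (H2-DMa, -0.34, SE 0.08), and Tap1 lost its call without GFP 4, GFP 5, GFP 6, Sox11 1, Sox11 2, Sox11 3 or Sox11 7 (adjusted p of 0.0646 to 0.0916). Psmb8 (0.47, SE 0.17) did not pass, but passed without GFP 3 (adjusted p = 0.0164, against up to 0.170 with another library left out).

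Of 8 mossy cell markers 3 fell, Ajap1 by 0.41 (SE 0.06) on the log2 scale, Ociad2 by 0.44 (SE 0.10) and Nmb, with 82.9% of its words its own, by 0.75 (SE 0.19). Of 12 Wnt pathway targets 1 rose (Apcdd1, 0.39, SE 0.07). Of the CA3 pyramidal neuron markers, Kcnq5 (-0.38, SE 0.14) passed only without GFP 3 or Sox11 3 and Iyd (0.35, SE 0.14) only without GFP 4, with lowest adjusted p-values of 0.0287 and 0.0270 and highest of 0.183 and 0.198 over the libraries left out. Ccnd1 (-0.21, SE 0.13) and Tcf7 (0.25, SE 0.19) did not pass. No member passed among CA1 pyramidal neuron markers (0 of 11), oligodendrocytes (0 of 15), their precursors (0 of 9), endothelium (0 of 13), pericytes and fibroblasts (0 of 14) or mitochondrial transcripts (0 of 9). The remaining SoxC members, Sox4 and Sox12, and the sex-linked gene Xist were not tested as lists. The median and the mean of the list differ in sign for mature granule neurons, neuropeptides, pericytes and fibroblasts and Wnt pathway targets.

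Markers of neighbouring tissue differed between libraries of the same group. The choroid plexus transcript Ttr, which encodes transthyretin, had 345860 normalized counts in GFP 3 and between 34.9 and 1312 in the other libraries. Tcf7l2, a thalamic and habenular marker, had 1661 normalized counts in GFP 1, 685 in Sox11 1 and 133 to 536 in the rest. None of the 11 choroid plexus markers and none of the 11 thalamus and habenula markers changed between the groups, with list medians of -1.71 and -0.29 and camera adjusted p-values of 0.135 and 0.384. Without GFP 3 the choroid plexus median was 0.01. The first principal component of the tested genes held 43.3% of the variance and separated the libraries numbered 1 to 3, at -73.1 to -3.09, from those numbered 4 to 7, at 8.15 to 42.3. The second held 17.4% and separated the GFP libraries, at 9.24 to 27.7, from the Sox11 libraries, at -26.7 to -14.1. Spearman correlations between libraries had a median of 0.992 within groups and 0.989 between groups.

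**Figure D3:**
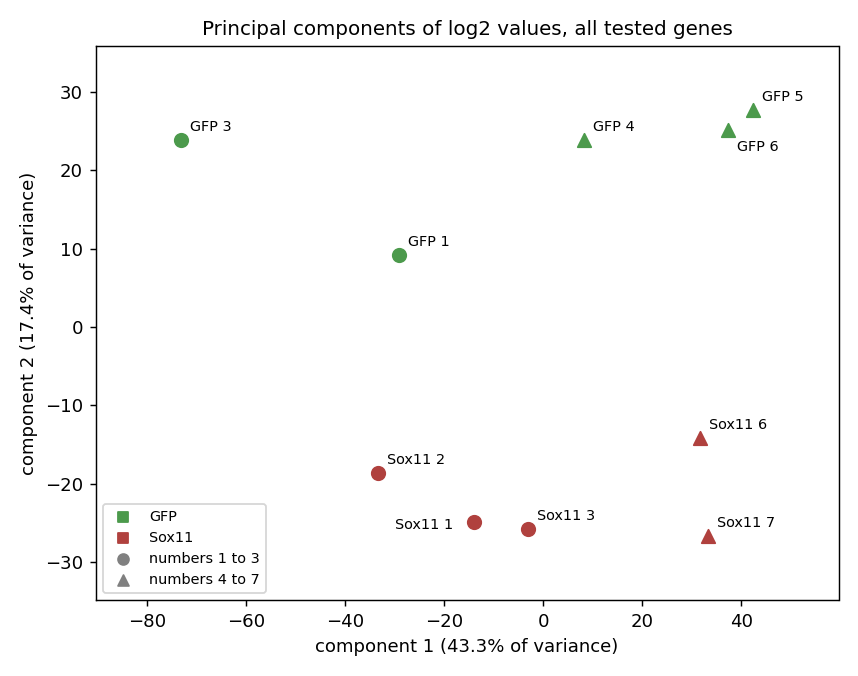
Scores of the 10 libraries on the first principal component (horizontal, 43.3% of the variance) and the second (vertical, 17.4%), from log2 values of 17007 genes. Green is GFP, red is Sox11, circles are libraries numbered 1 to 3 and triangles those numbered 4 to 7, and every GFP library lies above every Sox11 library on the second component.

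**Figure D4:**
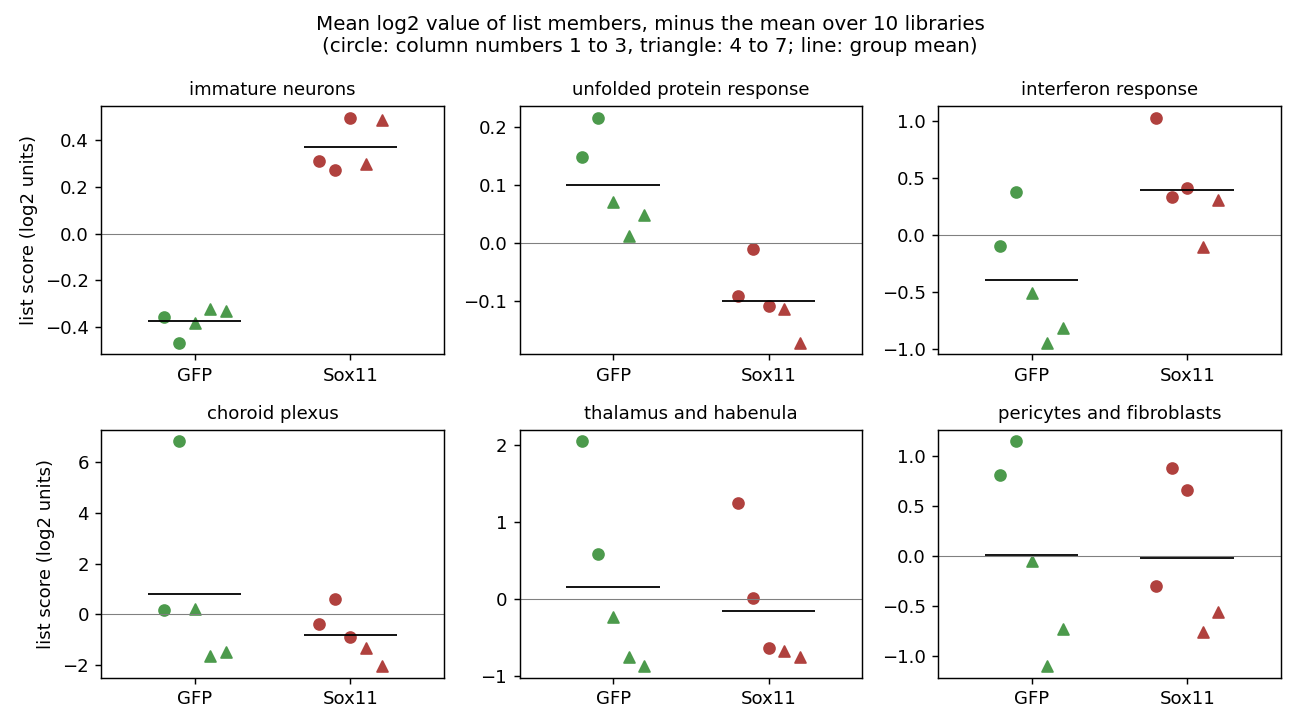
List scores per library, the mean log2 value of a list's members minus the mean over the 10 libraries, for 6 lists, with GFP in green, Sox11 in red, circles for numbers 1 to 3, triangles for 4 to 7 and lines for group means. Scores of immature neurons do not overlap between the groups, and GFP 3 lies at 6.84 for the choroid plexus.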

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

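The tests of choroid plexus for the interferon genes, of neighbouring tissue for the column numbers and of random divisions for the interferon list were chosen after the result was seen, and the choroid plexus test is the last of 4 tried, after 3 that were set aside because they rested on GFP 3, had an outcome nearly fixed by the design, or used total levels and did not decide.

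The number of genes changed is not explained by dividing the libraries by chance, since 1 of 100 divisions into 5 and 5, the real one, called 3234 genes or more, and the highest of the others called 626. That highest division is the one that parts the libraries numbered 1 to 3 from those numbered 4 to 7. It was noticed in these same data, so its high count is no separate evidence of a structure of the samples. For the number of gene lists chance cannot be excluded. The real division called 10 lists, 63 of the 100 divisions called at least as many, and the highest of the others called 22. The division by column numbers itself called 18, so these counts do not measure chance alone.

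In 306 groups of 5 values, 13 had a library far from the other 4, where chance gives about 15.3 (1 in 20). Sox11 stood apart in GFP 5 (1633.7 normalized counts) and in Sox11 3 (20434). Also apart were Glra3 (255.7 normalized counts) and Tap1 (172.91) in Sox11 6, Hapln4 (1450), Ajap1 (1717.7) and Sst (2763.4) in Sox11 7, Draxin (198.24) and Prox1 (20946) in GFP 5, Tcf7l2 in Sox11 1 (684.89) and Folr1 in GFP 3 (2122.7). The list scores of glutamate receptors in Sox11 6 (-0.002001) and of the choroid plexus in GFP 3 (6.843) stood apart as well.

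The genes that differ between libraries numbered 1 to 3 and 4 to 7 number 1880 with the group in the model. A difference in library depth is argued against, since 1697 genes still differed after every library was thinned to the smallest total, 45100154 reads. Neighbouring tissue carried over with the dissected dentate gyrus is a candidate explanation. The medians of 4 lists were at least 0.3 log2 units higher in the libraries numbered 1 to 3. They were 2.94 for choroid plexus, 0.98 for thalamus and habenula, 1.13 for pericytes and fibroblasts and 0.44 for endothelium. The division was noticed in these same data, so the lists are no separate support. The choroid plexus value rests largely on GFP 3 (list score 6.84, Ttr at 345860 normalized counts). GFP 4 (0.191) lay below Sox11 2 (0.605) but above GFP 1 (0.155), Sox11 1 (-0.399) and Sox11 3 (-0.892). Thalamus and habenula scores were highest in GFP 1 (2.06) and Sox11 1 (1.25). Of the markers on the 4 lists Tac2, Lef1, Dcn and Cspg4 are also on other lists, and other lists differed between the sets too, among them the interferon response (median 0.69, 27 of 28 members higher in 1 to 3), reactive astrocytes (0.67), antigen presentation (0.61) and mature granule neurons (-0.27). So did GABA receptors (-0.19), voltage-gated channels (-0.14) and leukocytes (0.66). Their medians between Sox11 and GFP had the same sign, at -0.19, -0.14 and 0.74. No label says what the numbers stand for, and no biological explanation was tested.

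The interferon response list had a median of 0.78, with 8 of 28 members higher and 1 lower, and it passed in camera with the preset correlation but not with an estimated one (adjusted p = 0.782) or in fry (0.127). Choroid plexus carried over with the tissue is argued against, since without GFP 3, which holds the most of it, its 11 markers summed to a difference of -956 normalized counts (Sox11 minus GFP, SE 464) against 3006 (SE 1021) for the interferon list. Outside GFP 3 most of the marker sum was not Ttr (176 of 2553 in GFP 1), so the sum does not measure choroid plexus alone. The median log2 fold change of its markers without GFP 3 was 0.01. The uneven spread of the column numbers over the groups is argued against as the whole cause, since the median was 0.59 with the set as a covariate, although it was 0.36 within the libraries numbered 1 to 3 and 0.88 within 4 to 7. Chance stays open. In 31 of 100 divisions the list had a p as small, but these were fitted without the column numbers. The list itself differed between those numbers (27 of 28 members higher in 1 to 3), so that count cannot decide. A response to Sox11 itself, or one that differs between the viruses used, stays open too and was not tested. Both groups received virus of the same serotype, so a response shared by both would not part them.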

How the results depend on the processing

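The tests that use the column numbers, leave out GFP 1 and GFP 3 together, or remove GC content and length trends were chosen after seeing the data. No gene among the 3234 changed sign under any setting run. Leaving out 1 library gave 2487 to 3268 genes changed (1280 to 1569 higher, 1175 to 1699 lower), 8 to 16 lists and a Sox11 log2 fold change of 2.89 to 3.15. Of 82 named genes that passed besides Sox11, 76 kept their call without each single library. With a threshold of 0.01, 1537 genes changed (816 higher, 721 lower). With the column-number set as a covariate over all libraries 4048 genes changed (2067 higher, 1981 lower). That fit kept 3196 of the 3234 calls and the 82 named genes. Without a filter 16 lists passed, and with estimated sample weights 17. In camera with an estimated correlation 0 lists passed (3 at an unadjusted p below 0.05), against 9 in fry and 11 in the rank-based camera. The libraries numbered 1 to 3 alone gave 1013 genes (589 higher, 424 lower) and, for the list interneurons, a median of 0.0685 with the opposite sign (adjusted p = 0.948, against 2.02e-06 in 4 to 7), and those numbered 4 to 7 alone gave 16 lists, with fewer libraries in each fit. For the other changes the cause was not tested.

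No paired analysis was possible from the sample titles, because the columns cannot be matched to them. A replicate block from the column numbers 1, 3 and 6 that the groups share, on 6 libraries, gave 42 genes (40 higher, 2 lower). Deviations of same-numbered libraries correlated at 0.194, 0.0675 and 0.415 across genes, GFP 1 and GFP 3 correlated best with Sox11 2, and GFP 6 with Sox11 6, so a shared number went with the best partner for 1 of 3. In simulation, where few genes changed and the adjusted threshold was therefore stricter than here, 8% of genes changed 1.2-fold and 96% of those changed 4-fold were recovered.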

Other observations

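The tests of gene families below, 264 over 132 families, were chosen after the gene results were seen, and the genes named after their values were seen.

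Among 367 tested zinc finger genes named Zfp, 86 rose and 12 fell, against 9.65% and 9.36% of all genes tested. Zfp46 rose by 1.14 on the log2 scale (SE 0.08), Zfp57, which acts in genomic imprinting, by 2.12 (SE 0.15), and Zfp184 by 1.57 (SE 0.13). Of 21 protocadherin beta genes, a cluster of neuronal cell adhesion genes, 10 rose and none fell, among them Pcdhb9 by 0.60 (SE 0.08). Of 13 heat shock protein 70 genes named Hspa 7 fell and none rose, with Hspa2 changed by -0.61 (SE 0.07) and Hspa1b by -0.84 (SE 0.15). Fisher's exact test gave adjusted p-values of 1.44e-12, 0.000783 and 0.00424 for these directions. The families named Atp (17 fell and 3 rose of 76) and Rab (16 fell and 3 rose of 67) had adjusted p-values of 0.0239 and 0.019. Among 100 divisions of the libraries a family median as far from 0 came up in 6 for Zfp and 4 for Hspa (highest other 0.256, real 0.202). It came up in 4 for Rab (highest other 0.0842, real 0.0704) and 1, the real one, for Atp. For Atp the highest other, 0.0738, lay close to the real 0.0742. These divisions covered 369 Zfp, 68 Rab and 77 Atp genes, slightly more than counted above. The family medians kept their direction under TMM scaling and quantile normalization. Under quantile normalization the counts shrank to 71 Zfp and 6 protocadherin beta genes higher, and 5 Hspa and 10 Atp genes lower. For Rab 11 fell and 6 rose. The Hspa median was -0.115 there against -0.202, and the Atp median -0.048 against -0.074. Under TMM scaling 90 Zfp and 11 protocadherin beta genes rose. Genes of a family are not independent, so these p-values are too small. Of the Hspa genes, shared sequence was computed for Hspa5 alone. Reads shared between close members that both fell, such as Hspa1a (-0.76) and Hspa1b (-0.84), therefore stay possible.

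For the 96 zinc finger and protocadherin beta genes that rose, GC content and length bias is argued against, since 87 were still called higher after those trends were removed. Reads shared between near-identical members are argued against for most, since 79 have at least 90% of their 31-base words in no other gene. The protocadherin beta genes were not counted apart in this check, so for them shared reads stay possible. Chance stays open for 390 genes as a set, the 367 and 21 above with 2 pseudogenes named Zfp, since 5 of 100 divisions of the libraries gave a median at least as far from 0 as the real 0.09, and the highest other was 0.0993. The protocadherin beta genes alone had a median of 0.35, which 1 of the 100 divisions, the real one, reached. An effect of Sox11 on these genes stays open as untested.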
